A study of Gallus gallus with 6 samples.

How the data were processed

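Chick embryos at Hamburger-Hamilton stage 18, embryonic day 3, were dissected by the submitters. The sclerotome is the ventral part of a somite that gives rise to the vertebral column, and each sclerotome has an anterior and a posterior half-sclerotome. Per the labels' protocols, half-sclerotomes were taken from somites 11 to 23, counted from the most recently formed, and pooled by type, with 100 half-sclerotomes in a pool. About 200 ng of total RNA per pool was selected for poly(A) and made into stranded libraries that were read as 50 nt single-end reads. There were 3 libraries of anterior and 3 of posterior half-sclerotomes. The labels do not say whether pools of different libraries came from separate embryos. Any spread between libraries that entered the authors' p-values may thus be partly technical. Sex of the embryos was not given.

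The submitters' processing notes name FastQC, TopHat2 2.1.0, Cufflinks 2.2.1, Cuffdiff and the genome build galGal4, without their roles. The deposited table has the header of a Cuffdiff gene comparison. Per the file headers, it gives 1 FPKM value per group (fragments scaled by transcript length and by the library's total of fragments), made by the authors from the libraries of that group, with no value per library. Per the file headers it also gives the authors' p-value and q-value for posterior against anterior, and a deposited log2 ratio. The annotation release, the counting options and the normalization between libraries are not given in the sources used here. FPKM depends on the total of each library and on transcript length, and on how reads shared by similar genes were assigned. The depth of the libraries is unknown, because the table holds no counts, so no counting interval or detection limit could be given.

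The table held 17108 gene rows, of which 10529 were tested by the authors and 6579 (38.5%) were marked as not tested. The deposited log2 column read as a spreadsheet error in 610 cells, so the ratio of posterior over anterior was computed here from the FPKM values. It matched the deposited log2 value within 0.001 in every row where both were finite except 1, which differed by 0.00158. Benjamini-Hochberg adjustment of the authors' p-values over tested rows gave their q-values to within 5.27e-07. The lowest p in the authors' deposited table was 5e-05, shared by 380 genes, with a q of 0.00139. Genes at this limit cannot be ranked by p. A gene was called when the authors' q was under 0.05, which was also the authors' own mark of significance. A gene marked as not tested was never called and says nothing about a difference. Among tested rows, 9548 had a gene symbol and 981 had none. Symbols are those of the table, some in older spelling. Loci are those of the table on galGal4, with 1 added to each start because the lowest start in the table is 0. A locus spans all transcripts that the authors' software merged, and 1648 tested rows shared their locus with another row, so reads of overlapping genes could be divided between them. Genes with a near-identical neighbour are likewise uncertain.

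Before the data were examined, 37 gene lists were fixed with 870 different members, of which 738 were matched to a row and 538 to a tested row. Of these members, 29 were matched through a synonym in a table of RefSeq gene names of assembly GRCg7b, used for names only. Where a symbol had several rows, the tested row of highest mean FPKM was used. Lists overlap in their members, so their results are not independent. For each list the share of called genes was compared with that among all other tested genes with a symbol by a 2-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 37 lists. The split of called members by direction was compared with that of other called genes in the same way. Calls were also counted with Benjamini-Hochberg adjusted over the list alone. The median log2 ratio of a list was placed as a percentile among 10000 random lists of the same size matched on mean FPKM in 10 bins. Genes are not independent replicates, and the correlation between genes cannot be estimated from 1 value per group. For that reason limma's cameraPR on ranks, with a preset correlation of 0.01, was run as an alternative and no estimated correlation could be used. The list step was tested on simulated data with 9548 genes, where it recovered 10 of 10 lists of 20 genes changed 2-fold, with their direction, and called 0 of 100 unchanged lists by Fisher's exact test. Of the same 100 unchanged lists, 5 had a median outside the central 95% of random lists. Simulated genes were drawn independently, so that share holds only for unrelated genes. Lists of genes that vary together may lie outside more often with no effect. Each simulated changed list moved in 1 direction as a whole, and some real lists have fewer tested members. All simulated genes had the same spread, and their calls did not depend on FPKM. Fisher's exact test was not matched on FPKM, so the 0 of 100 does not cover real lists whose expression differs from that of other genes.

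Named genes followed a rule fixed before the data were examined. In each direction the 12 genes with a symbol, q under 0.05 and at least 1 FPKM in the higher group that had the largest log2 ratio were named. All measured members of the lists of known posterior and anterior markers were added, as were up to 3 called members per direction of each other list, by lowest q and then largest ratio. Of lists with no called member, up to 2 members of highest FPKM could be named. Any other gene named in the text was chosen after its value was seen. Alternatives were other q thresholds, other corrections, minimum levels and folds, pseudocounts of 0.1 and 1, a re-centred ratio, counting each symbol once, and, chosen after seeing the data, leaving out chromosome Z or leaving out the crest, neuron and muscle lists. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.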

Results

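RNA of anterior and posterior half-sclerotomes from stage 18 chick embryos was compared, with 3 libraries per group. The comparison addresses which genes differ between the part of the sclerotome that neural crest cells and motor axons cross, the anterior one, and the posterior part that they avoid. All levels are the authors' FPKM values, 1 per group, so no replicate error can be given beside a level. The authors' q is the only measure of error. How the libraries entered it is not given in the sources used here, so q does not show how far the 3 libraries agreed for a gene.

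UNCX, a homeobox gene of posterior sclerotome, had the largest ratio among called posterior genes, at 1.45 FPKM in anterior and 87.8 FPKM in posterior half-sclerotomes (60.5-fold, q = 0.00139 in the authors' deposited table). TBX18, a T-box gene of anterior sclerotome, was at 32.5 FPKM in anterior and 3.10 FPKM in posterior (10.5-fold, q = 0.00139 in the authors' deposited table). On galGal4, UNCX lies on chromosome 14 from 2397872 to 2404127 and TBX18 on chromosome 3 from 76646414 to 76672046. In the authors' deposited table, 376 genes were higher in posterior and 368 in anterior half-sclerotomes among 10529 tested (7.07% in all), at q under 0.05. A difference of at least 2-fold was reached by 132 posterior and 177 anterior genes, and one of at least 4-fold by 24 and 47. On chromosome Z, 46 genes were higher in posterior and 17 in anterior, a split that differed from that of other called genes (Fisher's exact test on the authors' calls, 2-sided p = 0.000193, adjusted p = 0.00597 over 31 chromosomes). This test was chosen after the values were seen. Under 35 Mb of chromosome Z, 10 genes were higher in posterior and 12 in anterior, and from 35 Mb on 36 and 5. That position was also chosen after the values were seen. Of the 31 chromosomes, 1 passed, and the next were chromosome 11 with 16 posterior and 4 anterior calls (Fisher's exact test, adjusted p = 0.168), chromosome 7 with 10 and 22 (adjusted p = 0.308) and chromosome 17 with 4 and 12 (adjusted p = 0.346). Without chromosome Z, the counts were 330 and 351. Of 5 tested genes placed on chromosome W, 0 were called in the authors' deposited table. Their median log2 ratio was -0.28, with 20% above 0.

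**Figure D1:**
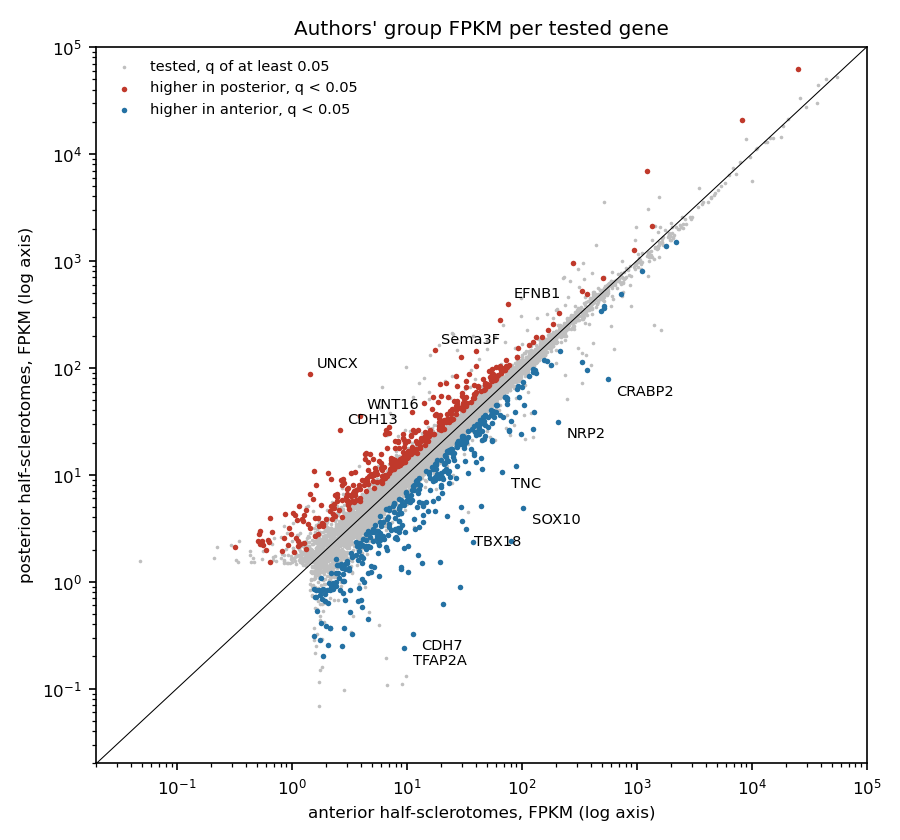
Authors' FPKM of each tested gene in anterior (horizontal) and posterior (vertical) half-sclerotomes, both on log axes, with the line of equality; red and blue points passed q under 0.05 and rows listed at 0 in a group are left out. UNCX lies farthest above the line among called genes, at 1.45 and 87.8 FPKM.

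Among the 12 leading posterior genes were the adhesion molecule CDH13 (2.65 and 26.0 FPKM, anterior and posterior), the Wnt ligand WNT16 (3.91 and 35.8), the secreted repulsive guidance ligand Sema3F (17.6 and 146) and the ephrin ligand EFNB1 (75.4 and 393). Each was at q = 0.00139 in the authors' deposited table. The matrix protein SMOC2 (2.07 and 10.4 FPKM), the exchange factor NGEF (0.318 and 2.12), the gap junction gene GJA4 (0.645 and 3.96) and the endothelial gene ESM1 (0.518 and 2.77, on chromosome Z) were at the same q in the authors' deposited table. PNAT3 and NAT, at 10.7 and 2.98 FPKM in posterior against 1.57 and 0.532 in anterior in the authors' deposited table, are neighbouring genes on chromosome 11 that may share reads. The row named 5_8S_rRNA was at 1224 and 6998 FPKM in the authors' deposited table. It is a ribosomal RNA, which poly(A) selection is meant to remove. Its ratio may therefore reflect how much of it was left in the libraries of each group, which was not tested. WNT16 shares its locus with another row.

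The leading anterior genes included transcription factors and adhesion molecules of neural crest cells. TFAP2A was at 9.52 and 0.240 FPKM in anterior and posterior (q = 0.0138), TFAP2B at 28.9 and 0.886, SOX10 at 103 and 4.92, and CDH7 at 11.3 and 0.326, with q = 0.00139 for the last 3 in the authors' deposited table. Tbx22, a T-box gene, was at 37.4 and 2.35 FPKM, RXRG, a retinoid X receptor, at 19.3 and 1.52, CNTN2, an axonal adhesion molecule, at 2.71 and 0.25, and COL25A1 at 3.36 and 0.323 in the authors' deposited table. CCDC180 was at 1.89 and 0.201 FPKM, and the row that the authors' deposited table names only Protein (ENSGALG00000009920) was at 20.8 and 0.625. REEP6 was at 4.60 FPKM in anterior and is listed at 0 in posterior in the authors' deposited table, so no fold is given.

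Genes known to mark each part of the sclerotome were measured first. Of 9 tested posterior marker genes, 7 were higher in posterior and 1 in anterior (8 and 1 adjusted over the list alone; share of called genes against other genes, Fisher's exact test on the authors' calls, adjusted p = 1.12e-07). Besides UNCX, CDH13, Sema3F and EFNB1, these were EFNB2 (3.55 and 10.7 FPKM, anterior and posterior), SPON1, which encodes F-spondin (51.8 and 93.8), and SEMA3A (20.1 and 27.7, q = 0.0190) in the authors' deposited table. The Notch ligand DLL1 went the other way, at 3.16 and 1.29 FPKM (q = 0.00261), and the proteoglycan gene VCAN, on chromosome Z, was at 33.3 and 42.6 FPKM (q = 0.0630) in the authors' deposited table. All 3 tested anterior markers were higher in anterior (3 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 0.000818). They were TBX18, the matrix glycoprotein TNC (67.8 and 10.7 FPKM) and the Eph receptor EPHA4 (21.5 and 15.1, q = 0.0121) in the authors' deposited table. RIPPLY1, RIPPLY2 and MESP2, which act in newly forming somites, were near or under 1 FPKM in both groups and were not tested by the authors.

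Genes of the sclerotome list lay toward posterior. Of 10 tested, 6 were higher in posterior and 0 in anterior (7 and 1 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 7.02e-05), with a median log2 ratio of 0.42. TCF15 was at 39.8 and 104 FPKM, GGMOXr1, a MEOX family homeobox gene, at 27.5 and 67.9, and MEOX2 at 27.5 and 45.7, each at q = 0.00139 in the authors' deposited table. PAX1, chosen after its value was seen, was at 367 and 490 FPKM (q = 0.0184) in the authors' deposited table. Early cartilage genes lay the other way, with 1 higher in posterior and 6 in anterior among 13 tested (1 and 8 adjusted over the list alone; Fisher's exact test, adjusted p = 4.31e-05) and a median log2 ratio of -0.59. The collagen gene COL9A1 was at 6.78 and 1.96 FPKM, MATN4, which encodes a matrilin, at 12.8 and 3.22, and COL11A1 at 39.9 and 23.6, whereas HAPLN1, on chromosome Z, was at 14.2 and 21.1 (q = 0.0257) in the authors' deposited table. MATN4, COL11A1 and TCF15 share a locus with another row. Tendon progenitor genes gave 1 call in 3 tested, FMOD, at 1.27 and 4.22 FPKM in the authors' deposited table (Fisher's exact test, adjusted p = 0.249).

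Markers of other cell types moved with the groups in both directions. Of 11 tested neural crest and Schwann cell precursor genes, 7 were higher in anterior and 0 in posterior (8 and 0 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 1.35e-05), and their median log2 ratio was -3.03. NGFR, also in that list and chosen after its value was seen, was at 80.8 and 79.3 FPKM (q = 0.963) in the authors' deposited table. Among 8 neuron genes, 4 were higher in anterior and 1 in posterior (4 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000209). The beta-tubulin gene TUBB3 was at 64.4 and 36.4 FPKM and the receptor gene RET at 5.80 and 2.48, but DCX, a microtubule-binding protein gene, was at 9.38 and 21.2, each at q = 0.00139 in the authors' deposited table. Of 15 dermomyotome and myotome genes, 8 were higher in anterior and 0 in posterior (11 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.35e-05; median log2 ratio -1.30). PAX3 was at 10.2 and 1.22 FPKM, MEF2C, on chromosome Z, at 13.9 and 3.64, and the acetylcholine receptor gene CHRNA1 at 9.63 and 2.89 in the authors' deposited table.

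Endothelial genes were higher in posterior in 8 of 19 tested and in anterior in 0 (10 and 0 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 7.51e-05), with a median log2 ratio of 0.54. VWF was at 0.620 and 2.45 FPKM, SOX18 at 3.94 and 7.36 and PLVAP at 26.7 and 44.2, and the vascular cadherin gene CDH5 had a log2 ratio of 0.72, in the authors' deposited table. No red blood cell gene was called among 6 tested (0 adjusted over the list alone and 0 at unadjusted p under 0.05), and the globin gene HBG1 was at 512 and 434 FPKM (q = 0.401) in the authors' deposited table. Lateral plate and limb genes gave 2 calls in 4 tested, both anterior (2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0437), TBX2 at 13.5 and 1.48 FPKM and PRRX2 at 1.84 and 0.684 (q = 0.0190) in the authors' deposited table. That list is not past the threshold with cameraPR in limma (adjusted p = 0.101) or at a q threshold of 0.1 (adjusted p = 0.0725). Of the remaining cell type lists, neural tube progenitors had 1 call in 3 tested (ZIC1, 6.43 and 23.9 FPKM) and intermediate mesoderm 1 in 1 (WT1, 2.69 and 1.47 FPKM, q = 0.0314) in the authors' deposited table. Notochord and floor plate (2 tested), surface ectoderm (5) and leukocyte genes (4) had 0 calls in the authors' deposited table. At an unadjusted p under 0.05 there, each of these 3 lists had 1 member, and adjusted over the list alone 1 notochord gene was higher in posterior, 1 surface ectoderm gene in anterior and no leukocyte gene in either.

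**Figure D2:**
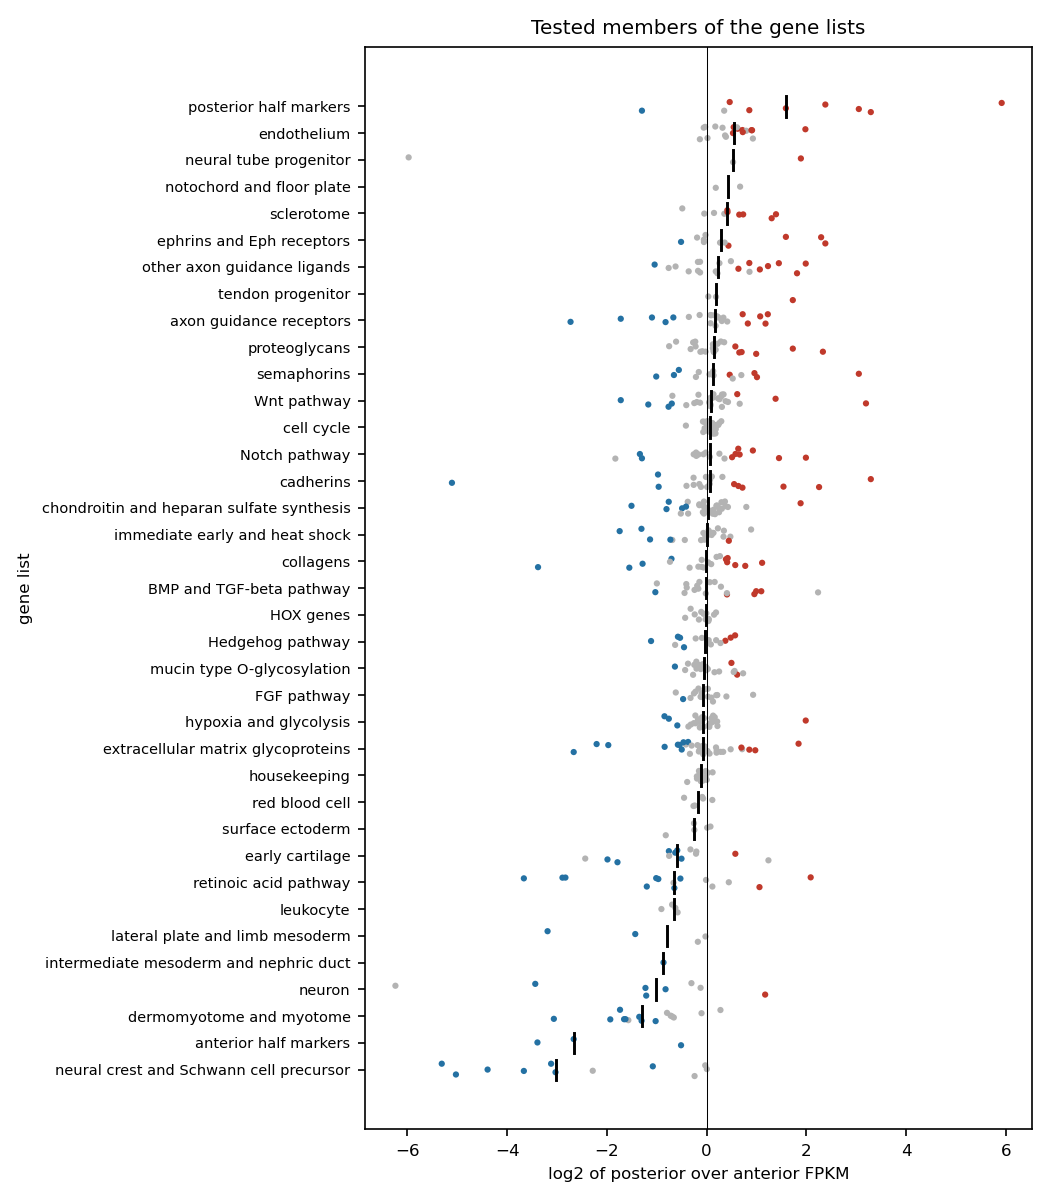
Log2 of posterior over anterior FPKM (horizontal) of each tested member of the 37 gene lists (vertical), in red or blue where the authors' q was under 0.05 and in grey otherwise, with a black bar at the median of each list. Medians run from -3.03 for neural crest genes to 1.59 for posterior markers.

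Axon guidance genes differed in both directions. Of 15 semaphorins, 4 were higher in posterior and 3 in anterior (4 and 3 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 0.000102). Besides Sema3F, SEMA3G was at 4.44 and 8.95 FPKM and SEMA7A at 7.35 and 14.3, while SEMA5B was at 39.1 and 24.8, each at q = 0.00139 in the authors' deposited table. Ephrins and Eph receptors gave 4 posterior and 1 anterior calls in 12 tested (5 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00206), and EPHA7 was at 1.62 and 7.98 FPKM in the authors' deposited table. Other guidance ligands gave 7 posterior and 1 anterior calls in 20 tested (8 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000102). They included VEGFA, at 6.60 and 26.2 FPKM, and FLRT2, at 6.94 and 24.4, against RSPO2, at 5.46 and 2.65, in the authors' deposited table. Of 22 guidance receptors, 5 were higher in each direction (7 posterior and 6 anterior adjusted over the list alone; Fisher's exact test, adjusted p = 7.85e-06). The semaphorin co-receptor NRP2 was at 208 and 31.4 FPKM, NRP1 at 44.8 and 21.0 and the netrin receptor UNC5C at 8.30 and 2.52, whereas the plexin genes PLXNA2 and PLXNA4 were at 3.40 and 7.97 and at 2.49 and 5.65 in the authors' deposited table. The neural crest and neuron lists lay toward anterior (median log2 ratios -3.03 and -1.02) and the endothelium list toward posterior (0.54). Whether guidance genes follow the share of those cells, and not sclerotome cells, was not tested.

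Matrix genes were called more often than other genes. Proteoglycans gave 6 posterior and 0 anterior calls in 24 tested (7 and 1 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 0.0113), with SMOC1 at 33.0 and 65.8 FPKM in the authors' deposited table. Of 35 matrix glycoproteins, 4 were higher in posterior and 9 in anterior (5 and 10 adjusted over the list alone; Fisher's exact test, adjusted p = 4.04e-06). The fibulin gene FBLN2 was at 39.7 and 143 FPKM, against OSF-2, which encodes periostin, at 125 and 27.0 and the laminin gene LAMA4 at 4.85 and 1.24, each at q = 0.00139 in the authors' deposited table. FBLN2 lies on chromosome 12 from 5783474 to 5867616. Of 20 collagens, 6 were higher in posterior and 4 in anterior (6 and 6 adjusted over the list alone; Fisher's exact test, adjusted p = 4.04e-06), with COL6A2 at 10.8 and 23.4 FPKM and COL23A1 at 77.6 and 26.5 in the authors' deposited table. Chondroitin and heparan sulfate synthesis genes gave 1 posterior and 5 anterior calls in 32 tested (1 and 5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0403), although the median log2 ratio of the list was 0.04. Its share of calls was not past the threshold at a q threshold of 0.1 (adjusted p = 0.163). The sulfatase genes Sulf1 and SULF2 were at 8.51 and 4.87 and at 21.7 and 12.8 FPKM, and the sulfotransferase gene NDST4 was at 0.630 and 2.33 in the authors' deposited table. Mucin type O-glycosylation genes gave 2 posterior and 1 anterior calls in 20 tested (3 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.227). Of 21 cadherins, 6 were higher in posterior and 3 in anterior (6 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 2.80e-05), with PCDH7 at 2.86 and 8.32 FPKM in the authors' deposited table. The cadherins include CDH7, named above among crest genes, and CDH5, also in the endothelium list. The crest and endothelium lists had median log2 ratios of -3.03 and 0.54.

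Genes of 5 of the 6 signalling pathways were called in both directions, and only 1 FGF gene was called, in anterior. Retinoic acid pathway genes gave 2 posterior and 8 anterior calls in 14 tested (3 and 8 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 1.04e-07). RXRG and ALDH1A3 of this list are also in the neural crest list, whose median log2 ratio was -3.03. Whether anterior calls of its other members follow crest content too was not tested. The binding protein genes CRABP2 and CRABP-I were at 561 and 78.8 and at 90.0 and 12.1 FPKM, whereas STRA6, a retinol transporter gene, was at 29.8 and 127 and CYP26B1, which encodes an enzyme that degrades retinoic acid, had a log2 ratio of 1.06 in the authors' deposited table. Notch pathway genes gave 7 posterior and 2 anterior calls in 19 tested (8 and 3 adjusted over the list alone; Fisher's exact test, adjusted p = 1.35e-05). The endothelium list, of cells that also express DLL4, lay toward posterior too, with a median log2 ratio of 0.54. The ligand gene DLL4 was at 1.07 and 4.24 FPKM and hairy1 at 19.9 and 54.4, against LFNG, which encodes a glycosyltransferase acting on Notch, at 81.0 and 32.0 in the authors' deposited table. Hedgehog genes gave 3 posterior and 4 anterior calls in 14 tested (4 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 7.02e-05), with GLI1 at 26.6 and 37.2 FPKM (q = 0.0326) and GLI3 at 27.6 and 18.5 in the authors' deposited table. At a q threshold of 0.01 the Hedgehog list was not past the threshold (adjusted p = 0.225). Wnt genes gave 3 posterior and 4 anterior calls in 29 tested (5 and 5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00745), and the secreted antagonist genes FRZB and SFRP1 were at 34.1 and 10.3 and at 87.1 and 38.7 FPKM in the authors' deposited table. BMP and TGF-beta genes gave 4 posterior and 1 anterior calls in 19 tested (6 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0170), with TGFBR2 at 2.73 and 5.83 FPKM and BMP7 at 3.65 and 1.79 in the authors' deposited table. FGF genes gave 0 posterior and 1 anterior calls in 18 tested (0 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 1), a share of 5.56% against 7.23% of other genes. The called gene was FGFR2, at 17.6 and 12.7 FPKM (q = 0.0190) in the authors' deposited table.

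Immediate early and heat shock genes gave 1 posterior and 4 anterior calls in 21 tested (3 and 5 adjusted over the list alone; Fisher's exact test on the authors' calls, adjusted p = 0.0252), with JUN at 129 and 38.4 FPKM and hsp70 at 48.0 and 29.0 in the authors' deposited table. Without chromosome Z genes, which removes DNAJA1, this list was not past the threshold (adjusted p = 0.0706), nor was it at a q threshold of 0.1 (adjusted p = 0.0653). Hypoxia and glycolysis genes gave 1 posterior and 3 anterior calls in 26 tested (1 and 3 adjusted over the list alone; Fisher's exact test, adjusted p = 0.162). No call was made among 13 HOX genes, 33 cell cycle genes and 17 housekeeping genes in the authors' deposited table, nor adjusted over each list alone, and 1, 3 and 0 of their members had an unadjusted p under 0.05 there. HOXB4 was at 321 and 366 FPKM (q = 0.604), PCNA at 609 and 606 (q = 0.993) and EF1A at 6382 and 6302 (q = 0.985) in the authors' deposited table. In all, 24 of 37 lists passed the test of their share of called genes (Fisher's exact test, adjusted p under 0.05), each with a higher share than other tested genes, and no list had a direction split that passed adjustment (lowest Fisher's exact adjusted p = 0.0925). With cameraPR in limma, which tests a shift in 1 direction, 10 lists passed, 8 of them among those 24. Toward posterior these were posterior markers, sclerotome, endothelium and cell cycle. Toward anterior they were anterior markers, dermomyotome and myotome, early cartilage, neural crest, neuron and housekeeping. No guidance, matrix or signalling list was among them. Housekeeping and cell cycle passed (cameraPR, adjusted p = 0.0481 and 0.0267) with no called member and median log2 ratios of only -0.12 and 0.07. The correlation between genes was preset and not estimated, so a pass with cameraPR may rest on a small common shift.

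**Figure D3:**
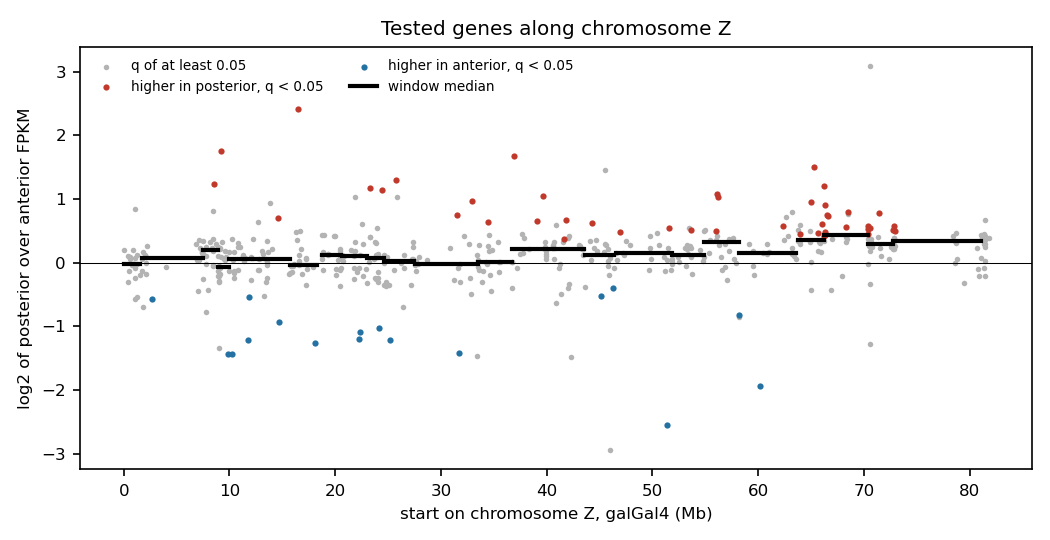
Log2 of posterior over anterior FPKM (vertical) of tested genes with a mean of at least 1 FPKM against their start on chromosome Z of galGal4 (horizontal, Mb), with black bars at the medians of windows of 20 genes. The median was 0.05 under 35 Mb and 0.25 from 35 Mb on.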

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

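Leaving out chromosome Z and leaving out the crest, neuron and muscle lists were chosen after seeing the data. No paired analysis was possible because the deposited table gives 1 value per group and none per library, and for the same reason leaving out each library and regrouping the libraries could not be run. Depth is unknown, so how far it limits the calls cannot be stated. At a q threshold of 0.01, 245 genes were higher in anterior, against 368 at 0.05, and 251 against 376 in posterior. Requiring at least 2-fold left 132 posterior and 177 anterior genes, by construction. Bonferroni-Holm over all tested genes left 0 in posterior and 0 in anterior, because the lowest p of 5e-05 is too large for any of 10529 tests, so this says nothing about stability (1699 genes had an unadjusted p under 0.05). Under the other settings the counts ran from 265 to 487 in posterior and from 273 to 473 in anterior. Leaving out chromosome Z gave 330 and 351, and leaving out the crest, neuron and muscle lists 375 and 349. Both only take called members out of the count, by construction, so they do not test dependence on cell content. Crest and muscle genes outside those lists, such as CDH7 and MYL4, stayed in. Of lists, 24 passed by share of calls, and 20 to 24 under the other settings. At a q threshold of 0.01, 20 passed, so lists besides Hedgehog also no longer passed there. With limma's cameraPR on ranks, which tests direction and not the share of calls, 10 passed, of which 8 were among those 24 and 2, cell cycle and housekeeping, were not. The number of lists with a median outside the central 95% of random lists was 16, and 16 or 17 with a pseudocount of 1, with a mean of at least 1 FPKM and without chromosome Z. Re-centring moves all ratios alike by 0.00468 and a pseudocount cannot turn a direction, so neither tests the direction of a named gene.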

Other observations

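All tests of explanations in this part were chosen after the result was seen, except the test of distal Z genes with q over 0.05. The genes of that test were still set by a position chosen after the values were seen. The 9 gene families looked at were also chosen after their values were seen, so their counts carry no test. Muscle filament genes lay toward anterior, with 11 of 18 tested called there and 0 in posterior. MYL4 was at 98.4 and 23.8 FPKM in anterior and posterior and TNNT3 at 8.90 and 1.38 in the authors' deposited table. All 3 tested TBX genes (TBX18, Tbx22 and TBX2) were higher in anterior. Of 6 tested connexin genes, 4 were higher in posterior and 0 in anterior, among them GJA5 at 7.01 and 28.0 FPKM and GJA1 at 55.6 and 88.2 in the authors' deposited table. Of all tested genes, 7.07% were called in either direction, and the endothelium list, of cells that also express GJA4 and GJA5, lay toward posterior too (8 of 19 called, median log2 ratio 0.54). The orphan receptor genes NR2F1 and NR2F2 were at 94.2 and 53.0 and at 180 and 105 FPKM, whereas NR2F6 was at 209 and 326 in the authors' deposited table. Of 8 tested SLC6 transporter genes, 3 were higher in posterior and 0 in anterior, with a median log2 ratio of 0.09. The serotonin transporter gene SLC6A4 was at 14.1 and 47.0 FPKM and the taurine transporter gene SLC6A6 at 4.37 and 14.1 in the authors' deposited table. SOX genes gave 2 posterior and 1 anterior calls in 10 tested (median log2 ratio 0.02), and forkhead genes 0 in 15 (median -0.02, with 3 at an unadjusted p under 0.05) in the authors' deposited table. All 3 N-acetyltransferase genes on chromosome 11, which are neighbours, and 2 of 3 iroquois and ZIC genes were higher in posterior, with 0 in anterior. An unnamed row near the 5_8S_rRNA row (ENSGALG00000026592) was at 25526 and 61643 FPKM in the authors' deposited table.

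Genes on chromosome Z, the sex chromosome of which male birds carry a pair, lay toward posterior. Over 493 tested genes with a mean of at least 1 FPKM the median log2 ratio was 0.1252, above every one of 10000 autosomal lists matched on FPKM (highest 0.0452), which argues against expression level. From 35 Mb on, 81.1% of 238 genes were above 0, and the median exceeded that of the proximal part by 0.2041. Random gene orders with their own best dividing position had a 95% limit of 0.170 and reached at most 0.327. The largest difference over all dividing positions of the actual order, which need not lie at 35 Mb, had a permutation p = 0.002. Together these values argue against 1 factor for the whole chromosome. The 197 distal genes with q over 0.05 still had a median of 0.2159, so a few strong genes do not carry the shift. Matched lists reached at most 0.0742, but the 35 Mb position was chosen after the values were seen. Those lists had no such choice, so the comparison with them does not test the shift. More male tissue in the posterior pools stays open for the distal part only if dose acts unevenly along Z, which was not tested. It would also need the groups to come from partly different embryos, which the labels do not give. With all anterior tissue taken as female, it would need a W-linked log2 ratio of -0.31 or lower. That lies within the bootstrap interval of 8 W-linked genes (median -0.01457, from -0.40 to 0.47). It is also near the median of the 5 placed on chromosome W alone (-0.28), so the value depends on which genes are counted. More male tissue would raise the dose of the whole chromosome, but the median under 35 Mb was 0.05 (bootstrap interval -0.0008 to 0.08). With an even effect of dose along Z, it leaves the difference between the parts unexplained. A regional variant between the embryos was not tested.

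Crest and muscle genes were higher in anterior. A lower share of sclerotome cells there would raise all other cell types alike. Lateral plate genes lay toward anterior, with a median log2 ratio (-0.80) below the central range of matched random lists. Medians of intermediate mesoderm (-0.87, 1 gene), leukocyte (-0.66), surface ectoderm (-0.25) and red blood cell genes (-0.16) were negative but inside that range, mostly without calls. The notochord and floor plate median was positive (0.43, 2 genes) and also inside that range. The endothelium list lay toward posterior (0.5433, quartiles of 0.25 and 0.76). That argues against a lower sclerotome share as the whole cause, but such a share may contribute. Neural tube tissue carried into the anterior pools cannot be told apart from crest and neurons in the anterior part, since only 3 neural tube progenitor genes were tested (median 0.5312), and SOX2 was at 6.74 and 0.107 FPKM (q = 0.680) in the authors' deposited table. Crest cells and axons in the anterior part, or uneven carry-over of myotome, are candidate explanations that the design does not separate.

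Genes of the sclerotome list such as TCF15 and PAX1 were higher in posterior. Whether only sclerotome cells make them was not tested. Dilution of sclerotome RNA by other cells in the anterior pools would lower early cartilage genes there too, if sclerotome cells made them. These had a median log2 ratio of -0.5885 with quartiles of -0.76 and -0.21, toward anterior. That argues against dilution as the whole cause only where cartilage genes come from sclerotome cells alone, which was not tested. Dilution may still contribute to the lower levels of sclerotome list genes in anterior. A difference between the anterior and posterior sclerotome cells themselves stays a hypothesis.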
